A study of Mus musculus with 16 samples.

How the data were processed

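Promoter-capture Hi-C was measured in 16 samples of mouse cells: ESC kept in 2i and Lif (day 0) and EpiLC (day 2), each from the lines DNMT_WT, DNMT_KO, TET_WT and TET_KO, with 2 replicates per group in the labels. Per the labels, chromatin was digested with HindIII and enriched for promoter fragments, and each knock-out line derives from its wild-type line. The series text speaks of replicates in general terms that differ from the number in the labels. Reads were trimmed with Trim Galore 0.6.5 and cutadapt 2.3 on GRCm38, per the submitters' processing notes; the aligner and the CHiCAGO version are not given in the sources used here.

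The deposited values are CHiCAGO interaction scores made by the authors, 1 score per pair of a promoter fragment (bait) and another fragment in each of 8 columns, 1 per group of line and stage. Whether and how the authors combined the 2 replicates of a group is not given in the sources used here. No values per sample were available, so no column has an SD and the sequencing depth per sample is unknown. From the values, each listed interaction reaches 5 in at least 1 column, scores are never negative, and no scaling between columns is stated. Of 260860 interactions, 257567 lie on 1 chromosome (cis) and 3293 join different chromosomes (trans); 23792 have a bait at the other end. For the genome build, 14530 of 14800 fragments (98.18%) lay within 2 kb of the RefSeq gene of the same symbol on GRCm38. Fragment length and GC content were not analysed here.

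A promoter's value was the mean asinh of the score over all its listed interactions, after quantile normalisation between columns, for promoters with at least 3 listed interactions. The 15344 interactions (5.882%) without a score in some column were left out. This gave 15677 promoters with a median of 11 interactions. A promoter's value therefore measures contacts that passed the calling threshold somewhere, not all contacts of the fragment. Promoters are named by the gene symbols of the bait; 186 baits named only as ultraconserved elements were tested but not named. Several members carry older symbols in the table, such as Tcfcp2l1 for Tfcp2l1.

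The comparisons, tests, gene lists and naming rules were fixed before the data were examined, with a fallback for values given as 1 column per group, which applied. The stage comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with cell line as a block over the 4 lines and Benjamini-Hochberg adjustment at 0.05. Its standard errors combine the spread of a promoter's stage difference between the 4 lines with a spread estimated from all promoters (eBayes). A promoter's standard error can therefore be larger or smaller than the spread of its own 4 lines gives. Since the knock-outs derive from the wild types, the lines are not fully independent. The median standard error was 0.1253. The knock-out comparisons and the stage by genotype comparison subtract columns and have no test. After the data were seen, a difference of 0.693 (a doubling for high scores) was chosen for counting promoters, and the difference between the wild-type lines was added as a background. Interaction counts at a score of 5 or more were compared between the stages with an exact permutation test over the 70 splits of the 8 columns, adjusted over the distance classes. Single cis interactions (244865 with all scores) were tested as the promoters were; for the knock-outs, interactions at 5 or more in 1 column and under 3 in the other were counted.

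The 17 gene lists were naive pluripotency, formative and primed epiblast, neuroectoderm, mesoderm and primitive streak, endoderm, hematopoietic, trophoblast, fibroblast, Hox clusters, other Polycomb-target regulators, germline genes silenced by DNA methylation, imprinted, clustered protocadherins, histone clusters, olfactory receptors, ribosomal proteins, and DNA methylation machinery. For the stage comparison each list was tested with camera of limma, with a preset correlation of 0.01 and with the estimated correlation, adjusted over the 17 lists. List members past the threshold were counted over all promoters and after adjustment over the list alone. For the knock-outs, the median of a list was placed among 10000 random lists of the same size, matched in 20 bins of mean promoter value, and called outside when beyond the central 95%; these percentiles were not adjusted over the lists. Neighbouring promoters of a cluster share contacts, which random lists do not reproduce.

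Named promoters of the stage comparison are the 10 largest rises and falls among those past the threshold whose ESC and EpiLC values do not overlap. Those of each knock-out are the 10 largest differences in each direction, by the mean of both stages, among promoters with at least 10 listed interactions and the same sign at both stages; those of the stage by genotype comparison are the 10 largest each way. Up to 4 members are named per list, together with list members past the threshold. The targeted genes are named wherever they could be tested, and for single interactions the 3 largest changes each way. The contacts within 1 Mb, the far contacts, Pramel1 in each column and members named for their values at the other stage were chosen after their values were seen. Some members that these rules name are not reported here.

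Alternatives tried were no scaling, division by the column mean, log2 of the score plus 1, no minimum and a minimum of 10 listed interactions, contacts within 1 Mb only, interactions with a mean score of 3 or more, the number of interactions at 5 or more in place of the mean, no trend in the variance, only the wild-type columns, and leaving out each line. Missing scores counted as 0 and TET_WT ESC as the control were added after the data were seen. So was subtracting the median of all promoters from the list medians under each scaling. Far contacts, over 5 Mb or between chromosomes, were counted in pairs of windows of 5 Mb.

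The methods were tested on simulated data with 15677 promoters, 100 of them shifted by 0.3 and another 100 by 0.6, in 20 draws. A shift of 0.3 was called in a mean of 2.15 promoters (0 to 5) and a shift of 0.6 in 40.4 (32 to 54), with mean estimates of 0.303 and 0.604, 0 calls in the wrong direction and 6.89% false calls. An earlier requirement that most shifted promoters be called was not met and was replaced by requirements on the estimate, the direction and the false calls; the simulation itself was not changed. In this simulation the stage test thus missed most shifted promoters. The adjusted threshold depends on the share of changed promoters, and the real comparison called 1391. Its recovery is therefore not given by this simulation. Of 200 unshifted lists of 30 promoters, 8 had a camera p under 0.05 and 7 lay outside the random 95% range. Tables were handled with data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.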

Results

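Promoter-capture Hi-C measures which distant DNA fragments lie close to gene promoters in the nucleus. It was used here on mouse embryonic stem cells (ESC) in the naive state at day 0 and on epiblast-like cells (EpiLC) derived from them by day 2. The series asks how adding and removing DNA methylation while cells leave pluripotency relates to contacts of regulatory elements, including elements used later in blood formation. Its samples came from 4 cell lines: DNMT_KO, which lacks the methyltransferases Dnmt1, Dnmt3a and Dnmt3b, TET_KO, which lacks the demethylating enzymes Tet1, Tet2 and Tet3, and a wild-type line for each (DNMT_WT and TET_WT). The labels list 16 samples in 8 groups of line and stage, with 2 replicates per group. The values analysed come as 1 column per group, so a single column has no SD, and its sequencing depth is unknown.

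The table listed 260860 interactions of 20017 promoter fragments, each reaching the authors' CHiCAGO score of 5, the usual calling threshold, in at least 1 column. The median distance between the ends of an interaction on 1 chromosome was 274.64 kb. Of all listed interactions, 43.97% reached 5 in 1 column only and 6.696% in all 8. Columns of the same stage lay together on the first principal component of the promoter values, which held 29.1% of the variance. The second component (22.9%) set the TET_KO columns apart, at −23.94 in ESC and −24.59 in EpiLC, from the other 6 columns, all above 0. The highest rank correlation between any 2 columns was that of DNMT_WT and DNMT_KO in EpiLC (Spearman correlation 0.756, across promoters).

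EpiLC had more contacts of 1 to 10 Mb than ESC in each of the 4 lines. Interactions spanning 1 to 10 Mb at a score of 5 or more numbered 2267.5 ± 741 per column in ESC (mean and SD over the 4 lines) and 4136.25 ± 404 in EpiLC, a ratio of 1.824. The DNMT_WT line went from 1515 to 4362, DNMT_KO from 2184 to 4129, TET_WT from 2083 to 3572, and TET_KO from 3288 to 4482. The exact two-sided permutation test over 70 splits of the 8 columns gave p = 0.02857, the smallest it can give, and 0.2 after Benjamini-Hochberg adjustment over the distance classes, so the difference did not pass the correction. These splits ignore that the columns are paired by line, and 4 pairs are too few for an exact paired test to reach 0.05. Counts over all distances were 87719.75 in ESC and 93106.5 in EpiLC, higher in EpiLC in 4 of 4 lines (exact permutation p = 0.1429). Contacts of 100 kb to 1 Mb, the largest class, hardly differed (ratio 1.021, exact permutation p = 0.7714). Contacts over 10 Mb and between chromosomes were more frequent in EpiLC in 3 of 4 lines (exact permutation p = 0.2571 and 0.2286). In TET_KO they numbered 650 and 669 in ESC and 471 and 637 in EpiLC.

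**Figure D1:**
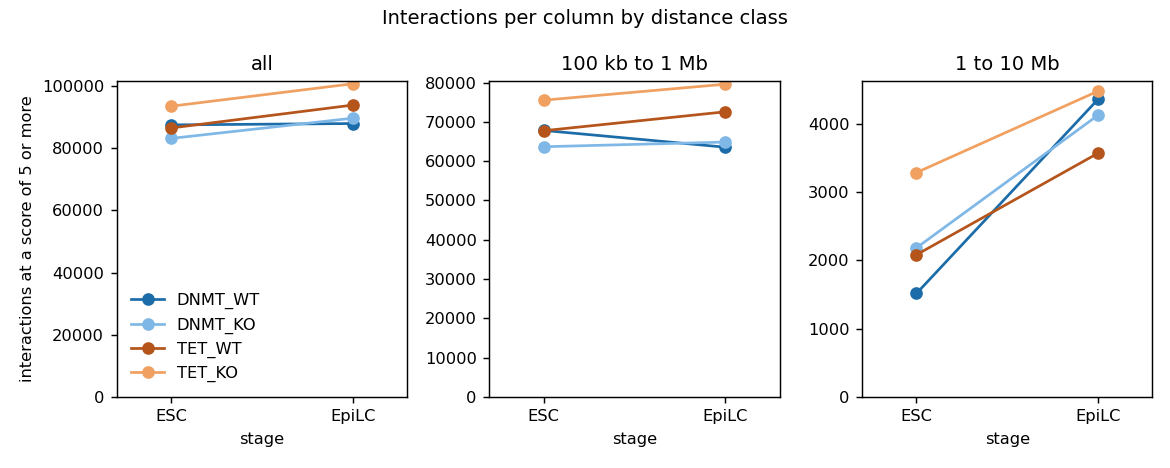
Number of promoter interactions at a CHiCAGO score of 5 or more (vertical axis, starting at 0) in the ESC and EpiLC column of each line, for all distances, 100 kb to 1 Mb, and 1 to 10 Mb. Each point is 1 column and each line joins the columns of a cell line; the 1 to 10 Mb counts lie between 1515 and 3288 in ESC and between 3572 and 4482 in EpiLC.

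The first comparison asks which promoters gained or lost contacts as naive cells became epiblast-like cells. Pcdh17, a protocadherin adhesion molecule of the nervous system (promoter fragment on chromosome 14, 84442219 to 84447115, GRCm38), rose by 1.16 ± 0.25, from 0.48 to 1.65. Values are differences of mean asinh score with limma's standard error, which draws on the 4 lines and on the spread of all promoters. Magi2, a synaptic scaffold protein (chromosome 5, 20694334 to 20705750), rose by 1.14 ± 0.24. Olfr1123, an odorant receptor (chromosome 2, 87408474 to 87418795), fell by 1.11 ± 0.14, from 2.38 to 1.26.

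Of 15677 promoters, 585 rose and 806 fell between ESC and EpiLC at an adjusted p under 0.05 (limma with cell line as block; 4321 had an unadjusted p under 0.05). Of all tested promoters, 2125 (13.6%) had their 4 EpiLC values entirely above or below their 4 ESC values, against 2.86% by chance; 988 of the promoters past the threshold were among them. Of the 1391 promoters past the threshold, 1366 moved the same way in both wild-type lines. The calls use these lines, so this is no separate check. The split between rises and falls depended on the scaling: without scaling between columns 905 rose and 442 fell, and after dividing columns by their mean 643 rose and 575 fell. The count was 600 without DNMT_WT, 25 without DNMT_KO, 460 without TET_WT and 373 without TET_KO. Among the 20 promoters named by the rule, 20 of 20 kept their call under both other scalings, while Chrm4 and Olfr1123 kept it whichever line was left out. Without a minimum of listed interactions 1 of 20 kept it and 21 promoters passed in all. With the number of interactions at 5 or more in place of the mean, 0 of 20 kept it and limma called 0 promoters (2973 with an unadjusted p under 0.05). With the wild-type columns alone it was 0 of 20 and 0 promoters as well (limma, 2360 with an unadjusted p under 0.05). The p-values rest on the spread between these 4 lines, of which 2 are knock-outs, combined with a spread estimated from all promoters.

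Among the 10 largest rises were Zic1, a zinc-finger factor of the neural plate (1.03 ± 0.29), and Tlx1, a homeobox gene needed for the spleen (0.96 ± 0.24). In both, the rise was smaller in the TET lines: Zic1 rose by 1.58 in DNMT_WT and by 0.32 in TET_WT, and Tlx1 by 1.60 and 0.59; these line differences were not tested. Qdpr, which regenerates tetrahydrobiopterin, rose by 1.02 ± 0.22, Arhgef10 by 0.98 ± 0.23, and Pvrl3, the adhesion molecule nectin-3, by 0.97 ± 0.27. Chrm4, a muscarinic acetylcholine receptor, rose by 0.93 ± 0.17, between 0.63 and 1.28 in the 4 lines. The other rises were the small nucleolar RNA copies U3.11 (1.05 ± 0.20) and SNORA17.260 (0.97 ± 0.20). Of these 10 promoters, 10 have an adjusted p between 0.00903 and 0.0386 in limma.

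The largest fall was that of Gm10979, a predicted gene on chromosome 4 (−1.42 ± 0.22). Dpt, which encodes the matrix protein dermatopontin, fell by 1.23 ± 0.23, between 1.16 and 1.32 in each line. Arhgap36, an activator of Hedgehog signalling, fell by 1.16 ± 0.25, Lrrn4, a leucine-rich repeat membrane protein, by 1.10 ± 0.19, and Kcnc2, a voltage-gated potassium channel, by 1.10 ± 0.24. The odorant receptors Olfr1097 and Olfr138 fell by 1.12 ± 0.29 and 1.11 ± 0.26. The U6 small nuclear RNA copies U6.835 and U6.462 fell by 1.18 ± 0.26 and 1.12 ± 0.19.

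**Figure D2:**
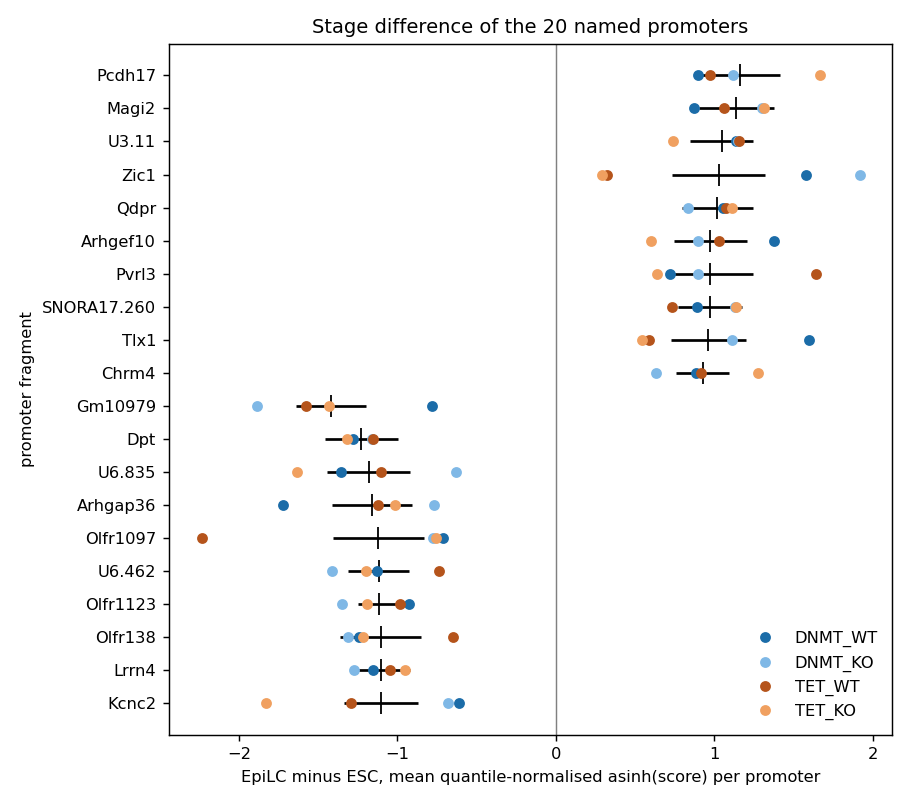
EpiLC minus ESC difference in mean quantile-normalised asinh score (horizontal axis) of the 20 named promoters. Coloured points are the 4 lines, the vertical tick is the limma estimate and the bar is plus and minus 1 standard error; all 4 lines lie on the same side of 0 for each promoter, with Pcdh17 at 1.16 and Gm10979 at −1.42.

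Pluripotency genes moved in both directions. Of 21 promoters of naive pluripotency genes, 2 rose and 2 fell: Klf4, a core naive factor, rose by 0.62 ± 0.14 and the orphan nuclear receptor Nr5a2 by 0.58 ± 0.16, while Nr0b1, another nuclear receptor of naive cells, fell by 0.79 ± 0.19 and Socs3, the feedback inhibitor of Lif signalling, by 0.59 ± 0.13. Adjusted over the list alone, 5 rose and 5 fell. Of 18 promoters of formative and primed epiblast genes, 4 rose and 0 fell: Sox3 (0.50 ± 0.12), the Fgf-responsive factor Etv5 (0.60 ± 0.14), Sall2 (0.37 ± 0.09) and Tead2 (0.32 ± 0.09). Adjusted over the list alone, 5 rose and 1 fell. Neither list differed from all other promoters in camera (adjusted p = 0.789 and 0.251 with the preset correlation).

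Lineage lists held few changed promoters each. Among 20 neuroectoderm promoters, Zic1, Nkx2-2 (0.44 ± 0.11), a ventral neural tube factor, and the Notch target Hes5 (0.39 ± 0.11) rose. Among 26 hematopoietic promoters, Lyl1 (0.46 ± 0.11) and the erythroid factor Klf1 (0.37 ± 0.10) rose, and Ikzf1, a regulator of lymphoid development, fell by 0.86 ± 0.18. Among 18 trophoblast promoters, Id2, an inhibitor of helix-loop-helix factors, rose by 0.79 ± 0.14 and Tcfap2c, an AP-2 factor, fell by 0.51 ± 0.09. Among 15 fibroblast promoters, 1 changed: Fbln2, a matrix protein, fell by 0.52 ± 0.15. Of 24 mesoderm and primitive streak promoters and 14 endoderm promoters, 0 passed limma's threshold, with and without adjustment over the list alone. Adjusted over the list alone, the counts of rises and falls were 4 and 1 for neuroectoderm, 3 and 2 for hematopoietic, 1 and 3 for trophoblast and 0 and 0 for fibroblast promoters. The camera adjusted p was 0.128 for neuroectoderm and 0.735 for each of the others.

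Of 70 promoters of other Polycomb-target regulators, developmental transcription and signalling genes, 6 rose and 0 fell: Nkx2-2 and Zic1 again, Irx1 (0.87 ± 0.25, higher in 3 of 4 lines), Barhl2 (0.54 ± 0.15), Otp (0.50 ± 0.14) and Lhx4 (0.35 ± 0.10), all homeobox genes apart from Zic1. The list missed the camera threshold (median 0.08, adjusted p = 0.0545 with the preset and 0.786 with the estimated correlation). Of 33 Hox promoters, Hoxc12 rose by 0.49 ± 0.10, while Hoxa13 fell by 0.66 ± 0.17 and Hoxd8 by 0.36 ± 0.10 (adjusted p = 0.789 in camera of limma). Of 27 germline promoters silenced by DNA methylation, Dazl, an RNA-binding protein of germ cells, fell by 0.77 ± 0.11, the meiotic genes Sycp3 and Syce1 fell by 0.42 ± 0.10 and 0.47 ± 0.14, and Tex11 rose by 0.42 ± 0.12 (adjusted p = 0.251 in camera of limma). These 3 lists gave the same counts when adjusted over the list alone.

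Among 38 imprinted promoters, Plagl1 (0.45 ± 0.12) and Asb4 (0.32 ± 0.09) rose and Cobl fell by 0.61 ± 0.16. Among 22 clustered protocadherins, Pcdhb22 rose (0.34 ± 0.09). Both lists kept these counts when adjusted over the list alone, with camera adjusted p of 0.735 and 0.462. Among 33 histone cluster promoters, Hist2h2aa2 rose (0.32 ± 0.09), and 0 passed over the list alone. Among 49 ribosomal protein promoters, 5 rose, such as Rps16 (0.39 ± 0.11), and Rpl31 fell by 0.44 ± 0.10, with the same counts over the list alone. The camera adjusted p was 0.0549 for both histone and ribosomal promoters (0.786 with the estimated correlation), and the histone list had a median of 0.64 in DNMT_KO but between −0.08 and 0.00 in the other lines. Of 15 DNA methylation machinery promoters, 0 passed limma's threshold over all promoters or over the list alone (camera adjusted p = 0.735).

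Olfactory receptors were the largest list and the only one of 17 to pass camera. Of 604 receptor promoters, 55 fell and 9 rose (75 and 12 adjusted over the list alone), and the median difference was −0.22. The median was negative in each line: −0.11 in DNMT_WT, −0.27 in DNMT_KO, −0.22 in TET_WT and −0.26 in TET_KO. The adjusted p was 4.94e-08 with the preset correlation and 0.786 with an estimated correlation. Swapping the stage labels within lines also called at least 1 list in each of the 8 possible arrangements, at most 5, so the list test does not set the real arrangement apart.

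At the level of single contacts, 506 of 244865 tested interactions rose and 265 fell (limma, adjusted p under 0.05; 40673 with an unadjusted p under 0.05), at 515 promoters. The count was 13 without DNMT_WT, 3 without DNMT_KO, 4 without TET_WT, and 0 without TET_KO (28240 with an unadjusted p under 0.05). The largest changes lay in contacts between regions many megabases apart. Hjurp, the chaperone that loads the centromeric histone (chromosome 1, 88276241 to 88278577), gained a contact with a fragment inside Xkr4 at 3608890 to 3609307, from 0 in each ESC column to scores of 13.06 to 19.95 in EpiLC (3.49 ± 0.30, adjusted p = 0.000184 in limma). U2.22 (3.22 ± 0.33) and U1.112 (3.13 ± 0.30), on chromosome 11, gained contacts over 14210 kb. Gm1992 on chromosome 1 lost a contact with the Ugt1a cluster of glucuronosyltransferase genes (−2.92 ± 0.29). Ugt1a1 lost 2 contacts across the same distance (−2.74 ± 0.34 and −2.60 ± 0.53), the second in 3 of 4 lines. These chromosome 1 contacts join windows at 0 to 5 Mb and 85 to 90 Mb, which were in contact at both stages. Contacts at 5 or more between them numbered 191, 288, 285 and 527 in DNMT_WT, DNMT_KO, TET_WT and TET_KO ESC. In EpiLC they numbered 294, 191, 344 and 370. The changes at Hjurp, Gm1992 and Ugt1a1 are thus those of single fragments within a pairing present at both stages.

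Within 1 Mb, a range chosen after the data were seen, 766 contacts rose and 499 fell. The largest rise was at Shh, the hedgehog morphogen. Its promoter (chromosome 5, 28463005 to 28467167) gained contact with a fragment 804.05 kb away inside Lmbr1, the gene whose intron holds the limb enhancer of Shh (29269034 to 29269235; 2.33 ± 0.31, adjusted p = 0.00476 in limma). The scores rose from 0.919, 0, 0 and 2.00 in the DNMT_WT, DNMT_KO, TET_WT and TET_KO ESC columns to 7.47, 7.85, 7.06 and 17.1 in EpiLC. The adjoining fragment (29269236 to 29270997) already scored 13.4, 7.93, 15.3 and 21.6 in the same ESC columns, and 17.7, 18.6, 17.9 and 28.25 in EpiLC. Other large rises were at Oscar (2.15 ± 0.39), Krt12 (2.12 ± 0.45), Bmp8a (2.11 ± 0.33) and Cadm3 (2.06 ± 0.37). Large falls were at Gm20408 (−2.12 ± 0.47), Pibf1, which lost 2 contacts with fragments in Klf12 (−1.99 ± 0.39 and −1.96 ± 0.27), Gm15935 (−1.94 ± 0.30), and between Olfr1115 and Olfr1135 (−1.94 ± 0.33).

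**Figure D3:**
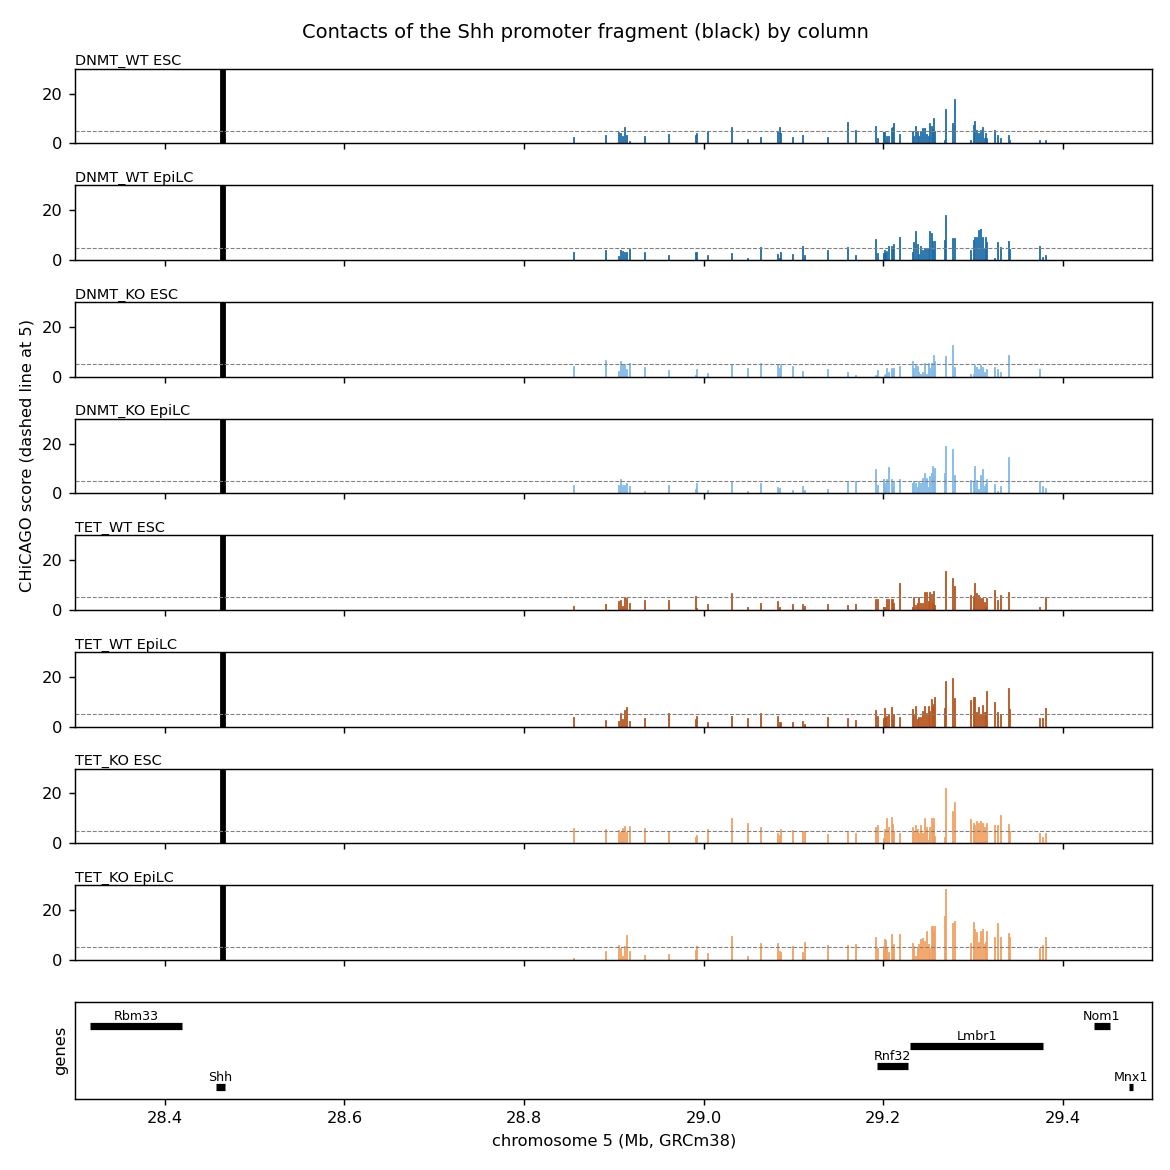
CHiCAGO scores (vertical axes, dashed line at 5) of the fragments contacted by the Shh promoter fragment (black bar) along chromosome 5 (GRCm38, Mb), 1 panel per column, with RefSeq genes in the lowest panel. The highest score in each of the 8 columns lies over Lmbr1, and the rise at 29269034 is 1 fragment among those over that gene.

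The second comparison asks how promoter contacts differ in cells without DNA methyltransferases. The targeted genes come first: Dnmt1, Dnmt3a and Dnmt3b had 1 tested promoter each, and their knock-out minus wild-type differences were −0.13, 0.13 and 0.01 in ESC and 0.17, −0.09 and 0.23 in EpiLC. Contacts of a promoter do not check whether its gene was deleted. The difference between DNMT_KO and DNMT_WT was about as large as that between the wild-type lines in ESC, was smaller in EpiLC, and did not repeat between the stages. Histone gene clusters, which encode replication-dependent histones, were lower in DNMT_KO ESC (median −0.47 over 33 promoters, and −0.27 with contacts within 1 Mb only) and higher in DNMT_KO EpiLC (0.17).

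In ESC, 328 promoters were higher and 335 lower in DNMT_KO by at least a doubling (0.693 on the asinh scale, a rule chosen after the data were seen), against 339 and 306 between the wild-type lines TET_WT and DNMT_WT. In EpiLC, 211 were higher and 181 lower, against 361 and 404. With 1 column per group these differences have no replicate check and no test. Across promoters, the ESC and EpiLC differences of DNMT_KO correlated at r = −0.11 (promoters are not independent replicates), and 21 promoters passed a doubling in the same direction at both stages while 40 passed in opposite directions. Without scaling between columns the share of higher promoters in ESC was 36.8% in place of 49.5%.

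The column labelled DNMT_WT ESC differed from the other DNMT columns in contacts within chromosome 4 over more than 5 Mb. It held 205 such contacts at a score of 5 or more, against 1755 in DNMT_KO ESC, 2222 in DNMT_WT EpiLC and 1933 in DNMT_KO EpiLC, and between 8 and 19 in the TET columns. It also held 26 contacts between chromosome 10 (85 to 90 Mb) and chromosome 4 (40 to 45 Mb) and 21 between chromosome 10 (55 to 60 Mb) and chromosome 8 (105 to 110 Mb), where each other column held 0. Each DNMT difference in ESC rests on that column, and so does the difference between the wild-type lines in ESC. With TET_WT ESC in place of that column, 868 promoters passed a doubling in DNMT_KO ESC.

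**Figure D4:**
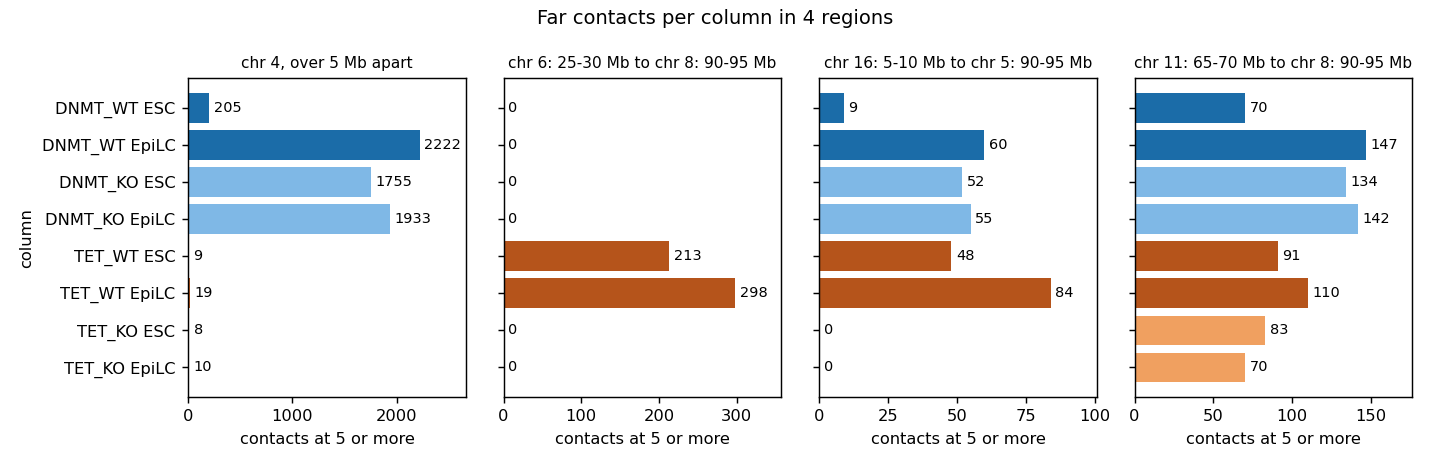
Number of contacts at a CHiCAGO score of 5 or more (horizontal axis, starting at 0) in each of the 8 columns (vertical axis). The panels show contacts within chromosome 4 over more than 5 Mb and 3 pairs of 5 Mb windows on different chromosomes. The chromosome 4 contacts number 205 in the column labelled DNMT_WT ESC and at least 1755 in the other DNMT columns; the pair on chromosomes 16 and 5 has 0 in TET_KO.

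Among promoters higher in DNMT_KO at both stages, Fam46b was first, by 1.39 in ESC and 0.24 in EpiLC, followed by Sfi1, a centrosome protein (1.21 and 0.17), and the chemokine receptor-like gene Ccr1l1 (0.99 and 0.39). U6.149 (0.68 and 0.65) and Trank1 (0.40 and 0.72) differed as much in EpiLC as in ESC or more. The others were 1700017D01Rik, 4930584F24Rik, Gm11399, the incretin receptor gene Glp1r (0.99 and 0.12) and the lysophospholipase Lypla2 (0.87 and 0.22). Fam46b and Lypla2 lie on chromosome 4. In the column labelled DNMT_WT ESC, Fam46b was at 1.09, against 2.29 to 2.53 in the other DNMT columns and 0.77 to 1.03 in the TET columns. Lypla2 was at 1.48 in that column, against 2.35 to 2.72 in the other DNMT columns and 1.59 to 1.66 in the TET columns. Lower in DNMT_KO at both stages were Ano7, an anoctamin (−0.67 and −0.58), Emx2os, the antisense transcript of the homeobox gene Emx2 (−1.10 and −0.12), Mir1897 (−1.06 and −0.08), the testis kinase Tssk5 (−0.17 and −0.95) and Cpne4, a copine (−0.84 and −0.29). AC150277.1, Gm11016, Rpl37 (−0.999 and −0.03), Pvrl3 (−0.60 and −0.42) and Lamtor3, a subunit of the lysosomal Ragulator complex (−0.90 and −0.11), completed the list. The sign turned under another setting at 1 stage for Gm11399, Lypla2, U6.149, Emx2os, Mir1897, Tssk5, Gm11016 and Rpl37, and at both stages for Cpne4 and Lamtor3.

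The histone list lay outside the range of 10000 random lists at both stages (percentile 0 in ESC and 100 in EpiLC), with 29 of 33 promoters lower in ESC and 28 of 33 higher in EpiLC. In ESC the largest differences were those of Hist1h2bg (−1.17), Hist1h3b (−1.03) and Hist1h4i (−0.88), and in EpiLC Hist1h4i was higher by 0.61 and Hist1h1d by 0.53. Olfactory receptors were higher in DNMT_KO ESC (median 0.14, percentile 100, 384 of 604 promoters) and lower in EpiLC (−0.04, percentile 0.01); between the wild-type lines their median was −0.02 in ESC and −0.13 in EpiLC. Ribosomal protein promoters were lower in ESC (−0.14, percentile 0.16), led by Rpl37 and Rpl39 (−0.84), and inside the random range in EpiLC (0.06). Clustered protocadherins were higher in EpiLC (0.14, percentile 99.6, 19 of 22), led by Pcdhb9 (0.37), and inside the random range in ESC (−0.10). The directions of the lists outside the range held under all 3 scalings.

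The remaining lists lay inside the 95% random range in DNMT_KO at both stages. Naive pluripotency promoters had medians of −0.12 in ESC and 0.11 in EpiLC, with Tdgf1, a Nodal co-receptor, at −1.12 and 0.40 and the pluripotency factor Sox2 at −0.67 and 0.13. The medians for ESC and EpiLC were −0.15 and 0.01 for formative genes, −0.06 and 0.01 for neuroectoderm, −0.01 and 0.05 for mesoderm, 0.02 and 0.01 for endoderm, and −0.03 and −0.07 for hematopoietic genes. Within the last list, Runx1, the master regulator of definitive blood formation, was lower in DNMT_KO by 0.75 in ESC and 0.97 in EpiLC (−0.75 and −0.97), and Lmo2 was at −0.96 in EpiLC. The wild-type lines differed as much at these promoters of 3 listed interactions each: TET_WT minus DNMT_WT was −1.27 in ESC and −0.875 in EpiLC for Runx1, and −1.045 in EpiLC for Lmo2. Trophoblast promoters had −0.09 and −0.05, fibroblast −0.07 and 0.04, Hox −0.03 and −0.02, Polycomb targets −0.05 and 0.06, imprinted −0.10 and 0.01, and methylation machinery 0.01 and −0.02. Germline genes silenced by DNA methylation had 0.10 and −0.02, among them Ddx4, a germ-cell helicase, at 0.41 and −0.52. Relative to all promoters under the same scaling, the sign of the median depended on the scaling for mesoderm in ESC and for endoderm and neuroectoderm in EpiLC, which all lay close to all promoters (−0.00594 to 0.00484).

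The third comparison asks the same of cells without TET enzymes. Tet2 and Tet3 had 1 tested promoter each, at −0.06 and 0.40 in ESC and −0.41 and 0.21 in EpiLC, and Tet1 had 0 tested promoters; as above, contacts do not check the deletion. Unlike DNMT_KO, TET_KO differed from its wild type in a way that repeated at both stages. Developmental regulators bound by Polycomb had stronger contacts in TET_KO (median 0.18 in ESC and 0.21 in EpiLC over 70 promoters). Zfp42, the naive marker also called Rex1, had weaker contacts (−0.78 and −1.15), but its level in TET_WT was above that in DNMT_WT by 0.66 in ESC and 0.53 in EpiLC.

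In ESC, 529 promoters were higher and 353 lower in TET_KO by at least a doubling, and in EpiLC 565 were higher and 398 lower. The ESC and EpiLC differences correlated at r = 0.391 across promoters, against 0.106 between the wild-type lines. At both stages, 202 promoters passed a doubling in the same direction and 29 in opposite directions, against 54 and 34 between the wild-type lines. The difference between the wild-type lines and that of DNMT_KO both use the column labelled DNMT_WT ESC. Whether that column lowers their agreement between the stages was not tested. Without scaling between columns the share of higher promoters in ESC was 77.1% in place of 60%. These differences rest on 1 clone or line per genotype and have no test.

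The largest differences were those of 1810030J14Rik on chromosome 1 (2.21 in ESC and 2.36 in EpiLC) and of the adjacent promoters Gm15552 (2.24 and 2.20) and Rheb, the GTPase that activates mTORC1 (1.97 and 2.16) on chromosome 5. At 1810030J14Rik, TET_WT minus DNMT_WT was 0.11 in ESC and −1.65 in EpiLC. Its values were 3.18 and 2.84 in TET_KO and 0.97 and 0.48 in TET_WT. In the DNMT columns they were 0.85 in DNMT_WT ESC and 1.71 to 2.14 in the others. The Rheb promoter fragment (24839664 to 24843098) had mean values of 2.24 and 2.33 in TET_KO and between 0.17 and 0.39 in the other 6 columns. Emx2os was higher by 1.87 and 1.70, Cntnap5c, a neurexin-family gene, by 1.72 and 1.42, and Gnai2, an inhibitory G protein subunit, by 1.46 and 1.58. The column labelled DNMT_WT ESC was also high at Gnai2 (2.63, against 2.57 and 2.62 in TET_KO). At Emx2os it was at 2.23, against 2.69 and 2.58 in TET_KO. Mir146, a microRNA gene, was higher by 1.27 and 1.60, but by −0.37 in ESC with contacts within 1 Mb only. 1700001L19Rik, Gm4956 and Slitrk3, a synaptic adhesion gene (1.09 and 1.22), followed. The small nuclear RNA copies U1.112 (−1.60 and −1.80), U1.113 (−1.32 and −1.86) and U6.660 (−0.79 and −1.58) were among the lower promoters. They lie together on chromosome 11. With contacts within 1 Mb only, U1.112 was at 0.05 and 0.40. In DNMT_KO ESC, U1.112 and U1.113 were at 0.69 and 0.43, about as low as in TET_KO ESC (0.72 and 0.43). Gm11634 (−0.99 and −1.40), Mob3c (−0.70 and −1.43), BC021891 (−0.98 and −1.07), Mfsd7a (−0.78 and −1.05), Cd83, a marker of mature dendritic cells (−0.87 and −0.93), and SNORA17.496 (−0.58 and −1.11) were also lower; the number of contacts of Mfsd7a at 5 or more was instead higher in ESC (0.42 on the log2 scale).

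The Polycomb-target list stood above all random lists at both stages (percentile 100), with 59 of 70 promoters higher in ESC and 54 of 70 in EpiLC. Between the wild-type lines it lay inside the random range (−0.08 in ESC, percentile 3.21, and 0.06 in EpiLC). A low level in TET_WT could still account for part of the ESC difference. Tbx15, a T-box factor of skeletal development, was higher by 1.48 in ESC and 0.95 in EpiLC, the eye and brain factor Pax6 by 0.48 and 0.99, and Onecut1 by 1.23 in ESC. Clustered protocadherins were also higher (0.14 and 0.20, percentiles 99 and 99.6, 18 of 22 at each stage), with Pcdhb9 at 0.39 and 1.19. For this list TET_WT minus DNMT_WT was −0.126 in ESC and −0.0251 in EpiLC, inside the random range. A level particular to TET_WT in ESC is thus not ruled out for the protocadherins. Mesoderm genes were higher in EpiLC (0.16, percentile 97.9) and inside the range in ESC (0.08); Isl1 was at 0.84 in ESC and 0.65 in EpiLC and Twist1 at 0.80 in EpiLC. That list shares 9 genes with the Polycomb list.

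Formative and primed genes were lower in TET_KO ESC (median −0.21, percentile 0.5, 12 of 18), with Utf1 at −0.65 in ESC and −0.38 in EpiLC and Zic5 at −0.63 and −0.49; in EpiLC their median was −0.09, inside the range. Hematopoietic genes were lower in TET_KO EpiLC (−0.15, percentile 1.72, 17 of 26), with the megakaryocyte integrin Itga2b at −0.88 and Ikzf1 at −0.74, but Erg and Runx1 at 0.75 and 0.72. Their median in ESC was −0.04. Histone clusters were lower in EpiLC (−0.24, percentile 0, 24 of 33), with Hist1h4b at −1.01, and at −0.03 in ESC; with contacts within 1 Mb only the EpiLC median of the histone clusters was −0.06. Olfactory receptors were lower in EpiLC (−0.04, percentile 0.18) and at 0.01 in ESC. The directions of these lists in EpiLC, and of the formative list in ESC, held under all 3 scalings.

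**Figure D5:**
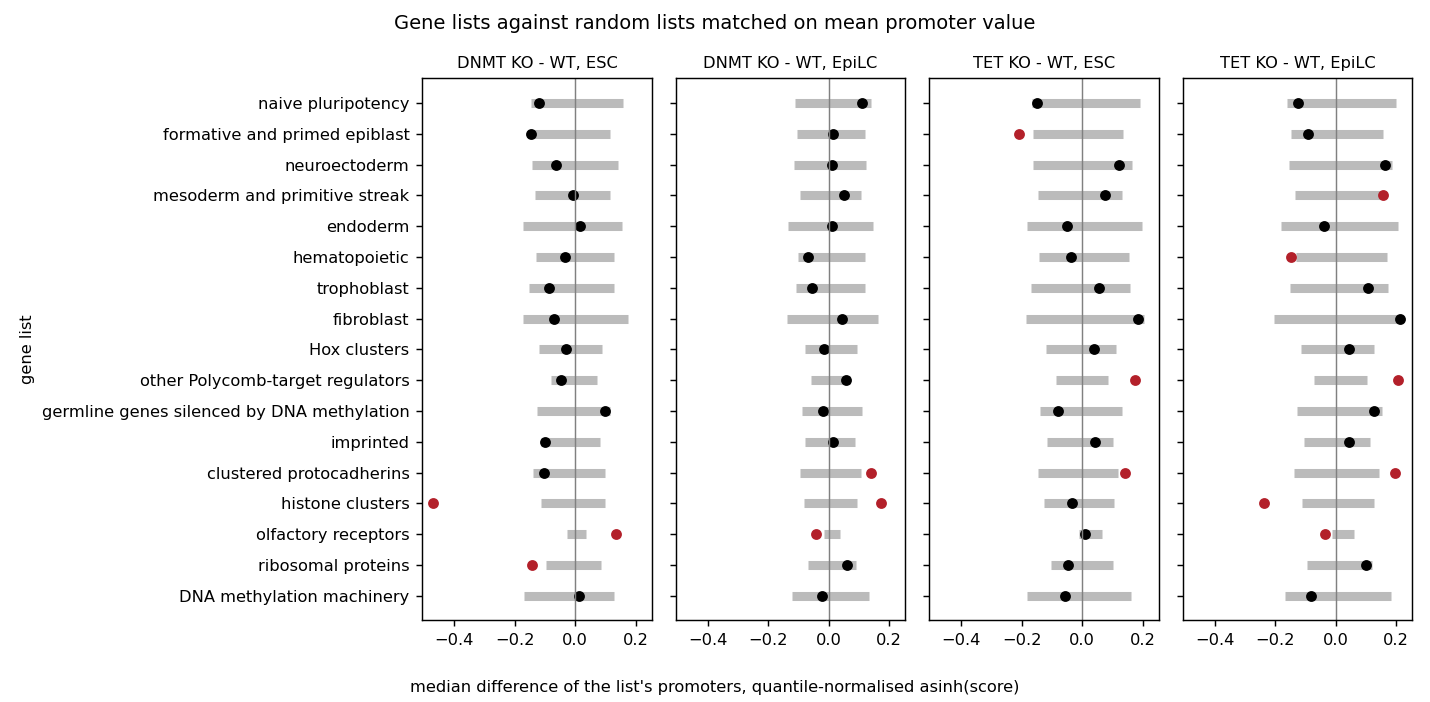
Median knock-out minus wild-type difference in promoter value (horizontal axis, quantile-normalised asinh score) of each gene list, 1 panel per knock-out and stage. Grey bars span the central 95% of 10000 random lists of the same size matched on mean promoter value; red points lie outside, such as the Polycomb targets in TET_KO (0.175 and 0.207) and the histone clusters in DNMT_KO (−0.471 and 0.173).

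The other lists lay inside the random range in TET_KO. Naive pluripotency genes had medians of −0.15 in ESC and −0.13 in EpiLC; besides Zfp42, the homeobox factor Nanog was at −0.87 and −0.50, while TET_WT minus DNMT_WT for Nanog was 0.60 and 0.29. Neuroectoderm genes had 0.12 and 0.16, fibroblast 0.18 and 0.21, trophoblast 0.06 and 0.11, endoderm −0.05 and −0.04, Hox 0.04 and 0.04, imprinted 0.04 and 0.05, germline −0.08 and 0.13, ribosomal −0.05 and 0.10, and methylation machinery −0.06 and −0.08. Single imprinted promoters moved apart between the stages, such as Calcr at 0.90 in ESC and −1.03 in EpiLC. Relative to all promoters under the same scaling, the sign of the median depended on the scaling only for endoderm in ESC (−0.0467, near 0 after dividing columns by their mean). Of 17 lists, 3 lay outside the random range in ESC and 6 in EpiLC in TET_KO, 3 and 3 in DNMT_KO, and 0 and 2 between the wild-type lines, the last being olfactory receptors (−0.13) and germline genes (−0.17).

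Single contacts favoured TET_KO. In ESC, 17781 interactions scored at least 5 in TET_KO and under 3 in TET_WT, and 13084 the reverse (ratio 1.36); in EpiLC the counts were 18332 and 14828 (1.24). After quantile normalisation the ESC counts were 14236 and 13733 and the EpiLC counts 15260 and 14533. DNMT_KO had 16747 against 17880 in ESC and 13074 against 13187 in EpiLC. Between the wild-type lines the counts were 17243 in TET_WT against 17901 in DNMT_WT in ESC (0.963) and 17051 against 12954 in EpiLC (1.32), so in EpiLC alone the background was as far from 1 as TET_KO. Over all distances, TET_KO had 1.081 times as many interactions at 5 or more as TET_WT in ESC and 1.073 times as many in EpiLC. From 100 kb to 1 Mb the ratios were 1.115 and 1.097, and between 1 and 10 Mb 1.578 and 1.255. TET_KO had fewer under 100 kb (0.8828 and 0.98) and between chromosomes (0.6991 and 0.5308), and over 10 Mb the ratios were 1.175 and 0.7104. Between the wild-type lines, TET_WT over DNMT_WT was 0.9886 and 1.067 over all distances, and 1.375 and 0.8189 between 1 and 10 Mb.

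The last comparison asks whether the stage difference itself differed between knock-out and wild type. Histone clusters showed this most clearly in the DNMT lines: their stage difference was higher in DNMT_KO than in DNMT_WT by a median of 0.56, in 32 of 33 promoters (percentile 100). Hist1h4i (1.496) and Hist1h3b (1.36) were among the 10 promoters with the largest such difference, with the ribosomal protein Rps23 (1.31), Gnai2 (1.65) and Gm5670 (2.20). Clustered protocadherins were also higher (0.26, 20 of 22, percentile 99.6) and olfactory receptors lower (−0.15, 385 of 604, percentile 0). At the other end were Pramel1 (−1.73) and Mir700 (−1.72) on chromosome 4, and the mitotic checkpoint gene Mad2l1 (−1.40). Each of these values contains the column labelled DNMT_WT ESC; Pramel1, for instance, was at 1.63 in it, at 3.09 to 3.37 in the other DNMT columns and at 0.07 to 0.19 in the TET columns.

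In the TET lines, 605 promoters had a stage difference higher in TET_KO by at least a doubling and 616 a lower one; in the DNMT lines the counts were 901 and 751. Without scaling between columns the TET share of higher promoters was 35.4% in place of 49.5%. The DNA methylation machinery was lower (−0.19, percentile 1.46, 10 of 15) and so were olfactory receptors (−0.04, percentile 0.9), while the Polycomb targets lay inside the random range (−0.03). The immune receptor Cd180 (1.21), the adenylate kinase Ak1 (1.01) and the RNA-binding protein Khdrbs3 (1.01) were among the highest, and Olfr69 (−1.48), Kbtbd8 (−1.23), Ugt1a1 (−1.14) and the muscarinic receptor Chrm2 (−1.09) among the lowest. Across promoters, the stage difference of the wild type correlated with that of its knock-out at r = 0.38 in the DNMT lines and 0.386 in the TET lines, and between the wild-type lines at 0.29. These differences were not tested.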

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

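The 3 tests of the chromosome 4 contacts in this part were chosen after that result was seen. The other tests were set down before their results were seen. That on the promoters kept under other scalings was set down after the other TET tests had been run. Its bounds were set beforehand, but its use of a counting interval was added after its value was seen.

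Far contacts within chromosome 4, over more than 5 Mb, numbered 1755 in DNMT_KO ESC against 205, 9 and 8 in the other ESC columns. That column stood apart from the other 3 by Dixon's gap ratio (0.887, above the 95% critical value); 1 of 16 such sets of 4 columns did, and chance gives about 1 in 20. The DNMT EpiLC columns held 2222 and 1933, so the column out of place among the DNMT columns is the one labelled DNMT_WT ESC.

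3 explanations for the few chromosome 4 contacts in the column labelled DNMT_WT ESC were tested. A column of lower sensitivity would lower all far contacts alike, but its chromosome 4 count was 0.106 of the median of the other DNMT columns, against 0.55 for 5 window pairs shared by the other columns. An effect of the DNMT enzymes at both stages would also lower DNMT_WT EpiLC, whose count was 1.15 times that of DNMT_KO EpiLC. An effect of the enzymes in ESC alone would not show in this ratio and was not tested. Cells of another background in this column stay open: its count of 205 lies between the highest TET column (19) and the lowest other DNMT column (1755), but that count prompted the test and so decides nothing. The labels name no other cells, and the reads were not analysed here.

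Histone clusters and olfactory receptors differed between the stages in DNMT_KO. The median difference from wild type moved by 0.644 between ESC and EpiLC for histone clusters, from −0.471 to 0.173, and by −0.176 for olfactory receptors, from 0.136 to −0.0404. Neither difference was tested, and both use the column labelled DNMT_WT ESC. For these lists that column was close to TET_WT ESC: the median of TET_WT minus DNMT_WT was 0.00644 for histone clusters and −0.0221 for olfactory receptors. With contacts within 1 Mb only the histone median in ESC was −0.269. The sign of each median was the same under the other scalings.

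The TET_KO differences that repeat at both stages cover 202 promoters. The tests exclude none of the technical explanations. The correlation between the stages was 0.392 without scaling and 0.391 with it, but a correlation across promoters does not respond to a shift of a whole column, so it decides nothing, although leaving out the scaling raised the share of higher promoters in TET_KO ESC from 60% to 77.1%. Without scaling, 83.2% of the promoters (168 of 202; 131 of 141 higher and 37 of 61 lower in TET_KO) still passed a doubling at both stages, with a counting interval of 77.3% to 88.1% that reaches the bound of 80% set beforehand. After dividing columns by their mean 86.6% did (175 of 202; 125 of 141 higher and 50 of 61 lower), with an interval of 81.2% to 91% above that bound. Both shares exceed that bound, but the requirement that the interval lie beyond it was added after the 83.2% was seen. Under that added requirement the scaling is not excluded, and it could account for a minor part. With contacts within 1 Mb only, 55.9% of the promoters (113 of 202; 75.8% of the 149 testable) still passed a doubling at both stages, so contacts over 1 Mb or between chromosomes could account for part of them. TET_WT lay farther than TET_KO from the DNMT columns in 25.7% of them (41.9% of all promoters), so a background particular to TET_WT could account for part as well. A loss of the TET enzymes and a difference between clones cannot be told apart with 1 line per genotype.

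The higher contacts of Polycomb-target regulators in TET_KO were set against 3 explanations. A low level in TET_WT as the whole cause was argued against. The list was above the random range in 4 of 4 comparisons of TET_KO with the DNMT columns (0.144 and 0.132 in ESC, 0.211 and 0.175 in EpiLC). These comparisons share the TET_KO columns and do not test whether TET_WT was low as well. Contacts over 1 Mb or between chromosomes were argued against by a percentile of 100 at both stages with contacts within 1 Mb only (0.207 and 0.208), and neighbouring promoters that share contacts by a percentile of 100 with 1 promoter per 5 Mb (0.195 and 0.226 over 55 promoters). DNMT_KO was itself higher than TET_WT in ESC (0.0998, percentile 98.7) but not in EpiLC (0.00626, percentile 39.4). In ESC, TET_WT minus DNMT_WT was −0.0846 (percentile 3.21, inside the random range). A low level in TET_WT could thus account for part of the ESC difference. A background of the TET_KO clone stays open, so an effect of the TET enzymes is a hypothesis.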

How the results depend on the processing

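Counting missing scores as 0, using TET_WT ESC as the control, testing single interactions within 1 Mb, and leaving lines out of the list tests were chosen after the data were seen; the other alternatives were planned. Where no cause is given below, the cause was not tested.

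Counts of promoters past a doubling are given in the order DNMT_KO in ESC, DNMT_KO in EpiLC, TET_KO in ESC, TET_KO in EpiLC, DNMT stage by genotype and TET stage by genotype, and then, as the background, TET_WT against DNMT_WT in ESC and in EpiLC. They were 663, 392, 882, 963, 1652, 1221, 645 and 765 as reported. With log2 of the score plus 1, where the same bound is a larger change, they were 300, 159, 380, 408, 879, 620, 259 and 343. Without a minimum of listed interactions they were 1678, 1337, 1867, 2140, 3258, 2746, 1671 and 1813, over 19394 promoters, and with at least 10 listed they were 112, 24, 221, 238, 380, 180, 105 and 144, over 8537. With a mean score of 3 or more they were 297, 159, 374, 381, 895, 493, 290 and 399. With the number of interactions at 5 or more in place of the mean they were 5387, 4449, 6129, 5553, 7140, 6389, 5403 and 5247. With missing scores as 0, DNMT_KO had 1045 in ESC and 630 in EpiLC, and the wild-type lines differed in 1253 in EpiLC. TET_KO had more such promoters than the wild-type background at both stages under each of these except, in EpiLC, the mean score of 3 or more and missing scores as 0 (1243 for TET_KO).

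The stage comparison called 1391 promoters. Without a minimum of listed interactions it called 21 of 19394, without a trend in the variance 437, and with missing scores as 0 it called 707. With the number of interactions at 5 or more, limma called 0 (2973 with an unadjusted p under 0.05), and with the wild-type columns alone, which leave 1 residual degree of freedom, it called 0 (2360 with an unadjusted p under 0.05). Leaving out each line gave 25 (without DNMT_KO) to 600 (without DNMT_WT). Among the values of promoters named between the stages, under all alternatives, 798 kept their direction and side of the threshold, 887 kept their direction only, and 0 reversed.

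The 1 to 10 Mb count difference between the stages was 1868.75; at a score of 10 or more it was 474.25 (exact permutation p = 0.171), and without each line 1542.67 to 2093.67 (exact permutation p = 0.1 each, the smallest that 3 against 3 columns can give).

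Single interactions called between the stages were 771: 1226 with log2, 101 with a mean score of 3 or more, 1265 within 1 Mb, and 0 (without TET_KO; 28240 with an unadjusted p under 0.05 in limma) to 13 (without DNMT_WT) on leaving out a line.

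Of the 17 lists, 1 was called between the stages, and 0 with the estimated correlation, where the olfactory median of −0.223 has an adjusted p = 0.786 with an estimated correlation in camera of limma. Without scaling 2 were called, Polycomb targets (0.156) being added, and within 1 Mb 4 were, with Polycomb targets (0.0941), histone clusters (0.157) and ribosomal proteins added. Leaving out a line called 2 to 4: Polycomb targets passed without DNMT_WT and without DNMT_KO (0.0825 to 0.119), and histone clusters without DNMT_WT, TET_WT or TET_KO (0.179 to 0.202). Olfactory receptors were called in each of these except with the estimated correlation. Without scaling, the olfactory median was 0.0833 in DNMT_KO ESC, 0.0824 in TET_KO ESC and −0.046 between the wild-type lines in EpiLC; less the median of all promoters these are 0.145, 0.0119 and −0.101, against 0.139, 0.0121 and −0.121 with scaling, so most of the move is a shift of all promoters. Within 1 Mb the histone median was −0.269 in DNMT_KO ESC and −0.0594 in TET_KO EpiLC. Of the list values for the knock-outs and the wild-type lines, 301 stayed close to those reported and these 5 moved.

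Of the values of promoters named for the knock-outs, 718 stayed close, 55 moved and 19 reversed. Within 1 Mb, Mir146 was at −0.371 in TET_KO ESC, and U1.112 at 0.052 in ESC and 0.4 in EpiLC; their reported differences rest on contacts over longer distances. With a mean score of 3 or more, Tssk5 was at 0.194 and Gm11016 at 0.428 in DNMT_KO ESC, and in EpiLC Gm11399 was at −0.0773, Cpne4 at 0.306, Rpl37 at 0.195 and Lamtor3 at 0.214. With the number of interactions, Gm11399 was at −0.348 and Lamtor3 at 0.322 in DNMT_KO EpiLC, and Mfsd7a at 0.415 in TET_KO ESC. With missing scores as 0, Lypla2 was at −0.0918 and Mir1897 at 0.0643 in DNMT_KO EpiLC. With TET_WT ESC as the control, U6.149 was at −0.265, Emx2os at 0.308, Cpne4 at 0.118, Gm11016 at 0.103 and Lamtor3 at 0.0106.

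No paired analysis was possible because the columns hold no replicate number; this concerns pairs by replicate, while the stage comparison already pairs the columns by line. Read depth per column is unknown, so its share in any difference was not analysed here.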

Other observations

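The gene families of this part were chosen after the data were seen, while the test on them was set down before its result; the other contacts between chromosomes were also looked at after the data were seen, and the counts over other arrangements of the columns were planned.

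Keratins, the filament proteins of epithelia, and serpins, a family of protease inhibitors, also had negative median differences between ESC and EpiLC. Of 47 keratin promoters 9 fell and 2 rose (median −0.14), and of 25 serpin promoters 5 fell and 0 rose (−0.15, adjusted p = 0.0118 in camera of limma for both). With the estimated correlation 0 of 12 families passed camera (adjusted p = 0.477 for these). Beta-defensins, antimicrobial peptides, had a median of −0.19 over 25 promoters (adjusted p = 0.0176 in camera of limma), and 207 promoters of Zfp zinc-finger genes had 0.07 (adjusted p = 0.0424 in camera of limma). The directions of these families held under all 3 scalings, and their adjusted p in camera of limma was also 0.477 with the estimated correlation. Thus 4 of 12 families passed with the preset correlation, and the stage difference of other tandem gene families may extend beyond the olfactory receptors; no test compared them with the olfactory receptors, and since swapped stage labels also call lists, this is a hypothesis.

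Families also differed between TET_KO and TET_WT. Keratins were lower at both stages (−0.188 and −0.118) and potassium channels, which set the excitability of neurons and muscle, were higher (0.0824 and 0.113), each outside the random range. In ESC, beta-defensins were lower (−0.317) and cadherins outside the clusters higher (0.245), and in EpiLC vomeronasal receptors were lower (−0.167). The wild-type lines differed the opposite way in ESC: TET_WT minus DNMT_WT was 0.246 for beta-defensins and −0.147 for cadherins outside the clusters, so a level particular to TET_WT is not ruled out. In EpiLC it was −0.0245 for vomeronasal receptors. In DNMT_KO ESC, vomeronasal receptors (0.201), beta-defensins (0.226) and solute carriers (0.0359) were higher, but TET_WT was above DNMT_WT about as far for vomeronasal receptors (0.165) and beta-defensins (0.246). In DNMT_KO EpiLC, keratins (−0.0948), serpins (−0.12) and solute carriers (−0.0329) were lower, and TET_WT was also below DNMT_WT for serpins (−0.166). Between the wild-type lines, keratins had 0.129 in ESC and −0.0335 in EpiLC.

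Contacts between chromosomes set some lines apart. Windows on chromosome 6 (25 to 30 Mb) and chromosome 8 (90 to 95 Mb) held 213 contacts in TET_WT ESC and 298 in TET_WT EpiLC. Windows on chromosome 17 (40 to 45 Mb) and chromosome 7 (40 to 45 Mb) held 53 and 66 in the same columns. The pair on chromosome 16 (5 to 10 Mb) and chromosome 5 (90 to 95 Mb) had 0 in both TET_KO columns and 9 to 84 in the other 6. The pair on chromosome 11 (65 to 70 Mb) and chromosome 8 (90 to 95 Mb) had 70 to 147 in all 8.

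Between the stages, 20688 to 24853 interactions per line scored at least 5 in EpiLC and under 3 in ESC, and 14638 to 19339 the reverse. Interactions gained in TET_KO at both stages numbered 1655, against 1307 if the stages were independent, and those lost at both stages 810, against 778.1. In the DNMT lines the counts were 484 against 869.8 and 462 against 936.6, and between the wild-type lines 1020 against 1184 and 590 against 933.5. Opposite changes were below independence in each pair: 1317 against 1806 in the DNMT lines, 744 against 2019 in the TET lines, and 1153 against 2128 between the wild types. Interactions are listed only if at least 1 column reached 5, so the columns cannot be independent. A count above or below the independent value therefore decides nothing about repetition between the stages.

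The stage result was set against other arrangements of the columns. Without the block, 1 of 35 splits of the 8 columns, the real one, called as many promoters (522, highest other 4), so chance can be excluded only in this model, which ignores that the columns are paired by line. With the line as block, which keeps the pairs, there are 8 arrangements, too few for a share under 0.05: for promoters 1 of 8 called as many (real 1391, highest other 0), for single interactions 1 of 8 (real 771, highest other 19), and for lists 8 of 8 (real 1, highest other 5).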
